A study of Drosophila melanogaster with 16 samples.

How the data were processed

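RNA of whole testes was measured on 16 Affymetrix DrosGenome1 arrays, 5 of wild type, 5 of bgcn and 6 of Os+bgcn, with about 5 µg of RNA per sample. Groups follow the sample titles; per the labels, the extraction text of the wild-type samples speaks of bgcn testes, but the spermatid list medians were 10.2 to 10.5 on these arrays and 5.19 to 5.59 on the bgcn arrays, so they do not hold the same tissue as the bgcn arrays. The deposited values are signal intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes; the version of MAS5 is not given in the sources used here. Each array had been scaled by the authors to a common trimmed mean. Detection calls and scanner images were not used here. The table holds 13966 probe sets and no array control probe sets.

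Probe sets were joined to current genes through the platform's gene identifiers. Of them, 12443 carry 1 gene symbol, 327 carry several and 1196 none. Of those with 1 symbol, 12394 matched by gene identifier, 4 by symbol and 38 by synonym, and 7 kept the platform's symbol. They name 10826 genes, 1216 of them with more than 1 probe set. A gene was represented by the probe set with the highest mean log2 value over all arrays. Of 22 other tested probe sets of the genes chosen for naming, 20 gave the same call and 2 another, those of scpr-B between both mutants and of Zasp52 between Os+bgcn and wild type. Zasp52 differed by 1.19 on the probe set used, by 1.07 (adjusted p = 7.0e-05) on another and by 0.49 (adjusted p = 0.21) on the last. Where the call was the same, the size could differ. In bgcn against wild type the other probe set gave 0.87 for kis, 0.68 for qin, 0.82 for ATPsynC, 2.41 for emb and 2.52 for nanos. Between both mutants it gave 1.10 for Nrt, -1.82 for Spn77Bb and, larger than on the probe set used, 1.81 for chinmo. A fold change named below holds for the probe set used and not for every probe set of the gene.

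Values were transformed to log2(signal + 18.8), the added pseudocount being the pooled 25th percentile of all values. Fold changes are on this scale, which understates the change of dim transcripts. A probe set was tested if its signal lay above 42.9, the pooled 40th percentile, on at least 5 arrays, which kept 10422 probe sets for 8565 genes and left out 3544. A linear model with 1 coefficient per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated errors that follow an intensity trend. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets in each contrast, and the threshold was an adjusted p of 0.05. Errors given with ± are standard errors for log2 changes and standard deviations for signals. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

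25 gene lists were fixed before the data were examined, as were the model, the filter, the first set of alternatives and the rule for naming genes; the spelling of 4 members was matched by hand afterwards. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 25 lists in each contrast. A list is said to pass by camera. limma's fry, which does not set a list against the other genes, was also planned and run. It passed some lists that camera did not, as in bgcn the spermatocyte regulators (fry adjusted p = 7.9e-08) and JAK-STAT genes (2.3e-10). Between both mutants it did not pass the ribosomal and oxidative phosphorylation lists (fry adjusted p = 0.091 each). Members passing were counted with p-values adjusted over all probe sets and over each list alone. The genes named are bgcn and upd1; in each contrast and direction the 8 genes with the largest absolute log2 fold change among those that passed, had no overlap between arrays of the groups, 1 gene symbol and a symbol other than a CG or CR number; and from each list and contrast up to 3 passing members with the largest change, or, where none passed, the member with the highest mean. Of the genes this rule gives, those printed were picked after their values were seen. X linkage was tested with Fisher's exact test, two-sided. Overlaps of contrasts that share arrays were set beside the product of both counts over the number tested, beside 100 simulations without effects, and beside a fit with the shared arrays split.

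The procedure was tested on simulated data with the same group sizes. In each contrast 67, 67 and 66 of the 10422 probe sets were changed by log2 0.5, 1 and 2, with independent noise per probe set. The filter was applied again to the simulated signals and left 9780 to 9792 in the fit. The real contrasts changed 20.5 to 71.4% of probe sets, and members of some lists correlate, at 0.39 for ribosomal proteins. The rates below therefore do not carry over directly to the real data. Recovery was counted among the changed probe sets that passed the filter again. For a log2 change of 1 it was 58.2% of 67 between Os+bgcn and bgcn. It was 63.1% of 65 between bgcn and wild type and 67.7% of 65 between Os+bgcn and wild type. For a change of 2 it was 96.7% of 60, 98.4% of 62 and 100% of 58. The others of the 66 were lost at the filter. Of 110, 120 and 118 calls, 7, 8 and 5 were false. Of 100 unchanged lists in each contrast, 6, 4 and 2 had a p under 0.05. The number of arrays limits the precision.

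Alternatives, apart from the replicate block, changed 1 choice at a time: quantile normalization, arrays centred on their medians, arrays centred on the cytosolic ribosomal protein genes (ribosomal centring), no pseudocount or a pseudocount at the pooled median, no filter or a filter at the pooled 60th percentile, the mean of all probe sets of a gene, no intensity trend, robust errors, array quality weights, a fit of the compared groups alone, replicate number as a block, and each array left out in turn. The fit with the block also left out the Os+bgcn array whose replicate number the other groups lack. A fit without bgcn arrays 1 and 2 and a fit with the accessory gland list score of each array as a covariate were chosen after seeing the data.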

Results

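Whole adult testes of Drosophila melanogaster of 3 genotypes were profiled on single-colour oligonucleotide arrays, with 5 arrays of wild-type testes, 5 of bgcn mutant testes and 6 of testes of the Os+bgcn genotype. bgcn (benign gonial cell neoplasm) acts with bam to end the dividing spermatogonial stage, and germ cells that lack it go on dividing without becoming spermatocytes. os (outstretched) is an older name of upd1, which encodes the secreted JAK-STAT ligand that hub cells send to the neighbouring germline and cyst stem cells. How Os was supplied is not given in the sources used here. The labels call the replicates biological. Each bgcn sample was made from 750 testes and every other sample from 150, so for differences particular to the bgcn group the number of testes and the genotype cannot be told apart.

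The median signal per array was 56.2 to 59.4 in wild type, 67.8 to 74.2 in bgcn and 66.95 to 74.5 in Os+bgcn. The 100 brightest probe sets held 26.9 to 28.2% of the summed signal in wild type, 20.5 to 29.1% in bgcn and 17.4 to 23.1% in Os+bgcn. Across the tested probe sets, which are not independent replicates, log2 values correlated at 0.932 to 0.944 within wild type, 0.870 to 0.960 within bgcn and 0.919 to 0.958 within Os+bgcn. Correlations between Os+bgcn and bgcn arrays were 0.798 to 0.907. Those of wild type were 0.185 to 0.267 with bgcn and 0.143 to 0.199 with Os+bgcn.

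The genes named by the genotypes were read first. upd1, on the X chromosome, had a signal of 396 ± 128 (SD, n = 6) in Os+bgcn, 9.6 ± 4.31 (n = 5) in bgcn and 11.6 ± 6.28 (n = 5) in wild type. It rose by 3.83 ± 0.21 (log2, SE) over bgcn, with a limma adjusted p of 3.5e-10, and by 3.75 ± 0.21 over wild type, with an adjusted p of 3.0e-12. Between bgcn and wild type upd1 differed by -0.09 (adjusted p = 0.74). The bgcn transcript, from chromosome arm 2R, had a signal of 67.7 ± 21.3 in bgcn, 84.8 ± 32.7 in Os+bgcn and 104 ± 34.6 in wild type. It differed from wild type by -0.50 ± 0.26 in bgcn (adjusted p = 0.092) and by -0.27 ± 0.25 in Os+bgcn (adjusted p = 0.34), and by 0.23 ± 0.25 between both mutants (adjusted p = 0.57). The bgcn difference from wild type passed at -0.74 with quantile normalization or with arrays centred on their medians, and at -0.62 without bgcn array 2 and -0.64 without wild-type array 4. Whether either probe set lies in the mutated or the added part of its gene was not analysed here, so these values check the Os label and not the bgcn label.

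**Figure D1:**
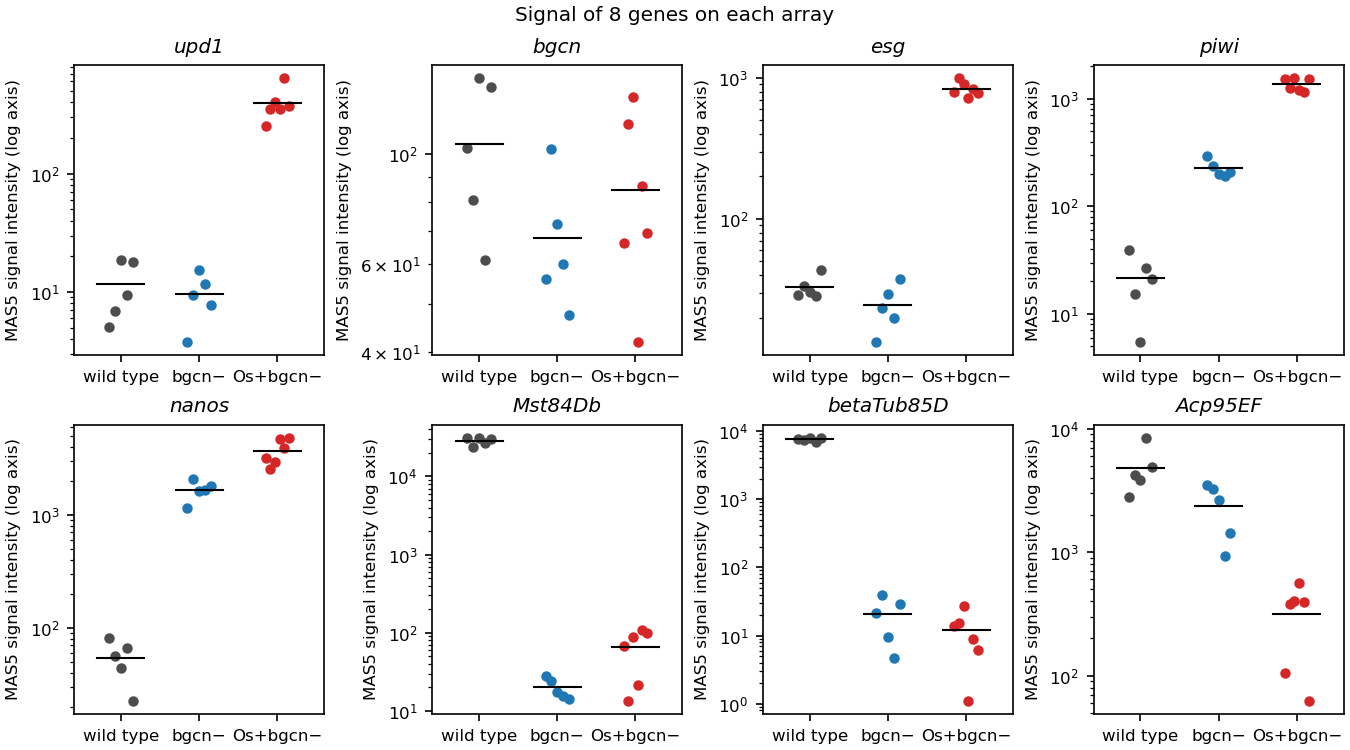
MAS5 signal intensity (log axis) of 8 genes on each array, with points for the 5 wild-type, 5 bgcn and 6 Os+bgcn arrays and a line at each group's mean. upd1 and esg lie above all other arrays on the 6 Os+bgcn arrays, piwi and nanos step up from wild type to bgcn to Os+bgcn, Mst84Db and betaTub85D are high in wild type alone, and Acp95EF falls from 2350 in bgcn to 317 in Os+bgcn on average.

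The comparison of Os+bgcn with bgcn testes asked which transcripts differ when the JAK-STAT ligand is added to the mutant testis. Genes of the stem cell niche, of early germ cells and of the piRNA pathway were higher in Os+bgcn, and markers of accessory gland, muscle, hemocytes and fat body were lower. esg, a Snail-family repressor needed to maintain hub and cyst stem cells, rose by 4.31 ± 0.16 to 836 ± 97.2 (SD, n = 6) from 24.7 ± 9.23 (n = 5), with a limma adjusted p of 8.4e-13. magu, a secreted modulator of BMP signalling, rose by 3.92 ± 0.28 (adjusted p = 9.4e-09), and piwi, the nuclear Argonaute of the piRNA pathway, by 2.50 ± 0.18 (adjusted p = 9.4e-09). regucalcin, a calcium-binding protein, changed by -2.98 ± 0.19 (adjusted p = 1.3e-09), and Acp95EF, a peptide of the accessory gland, by -2.96 ± 0.46 (adjusted p = 0.00012).

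Other genes among the largest differences of this comparison were Uhg1, a host of small nucleolar RNAs, at 3.79 ± 0.22, and Hesr, a Hairy-related repressor, at 3.03 ± 0.19. ImpL2, a secreted antagonist of insulin-like peptides, rose by 2.84 ± 0.17, and metro, a membrane-associated guanylate kinase, by 3.02 ± 0.34, or 2.72 ± 0.41 on its brighter probe set, which the alternatives used. scpr-B, of the cysteine-rich secretory protein family, rose by 4.59 ± 0.30 on the probe set used, while its other probe set differed by 0.30 (adjusted p = 0.48). On the lower side stood Anp, an antimicrobial peptide of the ejaculatory duct, at -3.23 ± 0.59, and Cyp4g1, the oenocyte enzyme of cuticular hydrocarbon synthesis, at -3.21 ± 0.54. The serpins Spn77Bb and Spn43Aa changed by -3.43 ± 0.87 and -2.80 ± 0.19, and the secreted glycoprotein gene ana by -2.99 ± 0.15. In each of these genes the arrays of both groups did not overlap.

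Of 10422 probe sets tested with limma, 2141 (20.5%) changed at an adjusted p under 0.05, 1212 higher and 929 lower in Os+bgcn, with 312 and 424 of them by at least 2-fold. The median of all tested probe sets was 0.03, and it moved to 0.43 with arrays centred on the cytosolic ribosomal protein genes, where 85.1% of the changed probe sets were higher against 56.6%. With the accessory gland list score of each array as a covariate, chosen after seeing the data, 351 probe sets changed. That score separated the groups, and the median standard error of the 2141 grew from 0.196 to 0.348 while their median size went from 0.83 to 0.70 and 97.5% kept their direction.

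Of the JAK-STAT genes and reported targets, 9 of 10 tested rose and 1 did not pass, also 9 adjusted over the list alone, with a median of 1.04. The list's camera adjusted p was 1.5e-07, and 0.00073 with an estimated correlation. upd1, which the genotype itself names, was the highest member of this list and of the hub list, and neither was tested without it. Besides upd1, apt rose by 1.32 ± 0.16 and chinmo, a BTB zinc finger gene needed by cyst stem cells, by 1.30 ± 0.17. Of 5 hub cell markers 4 rose, among them upd1, which the genotype itself names, and 1 fell. The counts were the same adjusted over the list alone, with a median of 1.56 (camera adjusted p = 0.00022, and 0.022 with an estimated correlation). The cell adhesion gene CadN rose by 2.54 ± 0.24 and the junction scaffold dlg1 by 1.56 ± 0.16. hh, the hedgehog ligand, changed by -0.63 ± 0.20 (adjusted p = 0.030). It was -0.63 to -0.55, with an adjusted p of 0.051 to 0.075, without bgcn array 1, 3 or 4 or Os+bgcn array 2, 3 or 6, and it did not pass with quantile normalization, with ribosomal centring, without bgcn arrays 1 and 2 or with the accessory gland covariate. Of 12 cyst stem and cyst cell markers 8 rose, 1 fell and 3 did not pass, also 8 and 1 adjusted over the list alone, with a median of 1.22 (camera adjusted p = 7.1e-05, and 0.0030 with an estimated correlation). Nrt, a neurotactin adhesion protein, rose by 2.53 ± 0.24, the cyst lineage transcription factor tj by 2.08 ± 0.35, and aop, an ETS repressor, by 1.61 ± 0.20. These lists are not independent, as 3 JAK-STAT genes, 2 hub markers and 6 cyst markers tested stand on another list too.

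Germline lists rose as well. Of 16 early germline and transit-amplification genes 9 rose, 12 adjusted over the list alone, and none fell, with a median of 0.64 (camera adjusted p = 2.0e-06, and 0.0010 with an estimated correlation). otu, needed for germ cell differentiation, rose by 1.73 ± 0.20, fs(1)Yb, which acts in somatic niche cells, by 1.58 ± 0.31, and hts, a fusome adducin, by 1.42 ± 0.27. Of 24 piRNA pathway genes 17 rose and 7 did not pass, also 17 adjusted over the list alone, with a median of 0.56 (camera adjusted p = 2.4e-09, and 0.00063 with an estimated correlation). After piwi, the helicase gene spn-E rose by 1.78 ± 0.14 and the Tudor domain gene vret by 1.58 ± 0.16. Of 48 DNA replication and mitotic cell cycle genes 21 rose and none fell, 26 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 2.2e-08, and 0.0011 with an estimated correlation). The mitotic kinesin Klp61F rose by 1.32 ± 0.15 and tum, a centralspindlin subunit, by 1.11 ± 0.19. Of 14 meiotic cell cycle genes 4 rose, 1 fell and 9 did not pass, 6 and 1 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.010, and 0.031 with an estimated correlation). Cks30A, a subunit of cyclin-dependent kinases, rose by 1.29 ± 0.16.

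Of 13 EGFR pathway genes 6 rose, 1 fell and 6 did not pass, the same adjusted over the list alone, with a median of 0.56 (camera adjusted p = 0.00093, and 0.0080 with an estimated correlation). spi, the ligand that germ cells send to cyst cells, rose by 1.45 ± 0.17 to 1092 ± 123 (SD, n = 6), and kek1, a feedback inhibitor, by 1.52 ± 0.32. Of 10 hedgehog pathway genes 2 rose, ci by 1.46 ± 0.22 and ihog by 1.15 ± 0.22, 1 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.18). Of 14 BMP and TGF-beta genes 1 rose, the type I receptor gene sax by 0.67 ± 0.18, and 3 fell, among them the inhibitory Smad gene Dad at -0.98 ± 0.21. The BMP list counts were 1 and 4 adjusted over the list alone, its camera adjusted p was 0.24, and its median of -0.08 turned to 0.31 with arrays centred on the ribosomal protein genes. Dad did not pass with that centring (adjusted p = 0.272) or without a pseudocount (adjusted p = 0.151).

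Most accessory gland, muscle sheath and hemocyte markers, and 6 of 12 fat body and antimicrobial genes, were lower in Os+bgcn than in bgcn. Of 17 accessory gland and ejaculatory duct markers 14 fell and 3 did not pass, 17 adjusted over the list alone, with a median of -2.43 (camera adjusted p = 2.8e-10, and 0.048 with an estimated correlation). Acp53C14b changed by -2.62 ± 0.49 and Acp63F by -2.59 ± 0.49, and Mst57Da, which stands on the spermatid list but is an accessory gland gene, by -3.07 ± 0.51. Of 17 muscle sheath markers 11 fell and 6 did not pass, 12 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 8.3e-07, and 0.0080 with an estimated correlation). bt, the muscle projectin, changed by -1.69 ± 0.25 and the myosin light chain Mlc1 by -1.67 ± 0.26. Of 11 hemocyte markers 7 fell and 4 did not pass, also 7 adjusted over the list alone, with a median of -1.07 (camera adjusted p = 0.00012, and 0.0060 with an estimated correlation), with Hml, a hemocyte adhesion protein, at -1.86 ± 0.25 and Pxn, peroxidasin, at -1.66 ± 0.35. Of those 12 fat body and antimicrobial genes 6 fell and 1 rose, the same adjusted over the list alone, with a median of -0.84 (camera adjusted p = 0.00056, and 0.044 with an estimated correlation). Drs, an antifungal peptide gene, changed by -1.91 ± 0.26 and the lipase gene Lip4 by -1.63 ± 0.27.

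The array medians of the accessory gland list were 8.80 ± 1.17 (SD, n = 5) in bgcn, 6.30 ± 0.74 (n = 6) in Os+bgcn and 7.81 ± 0.84 (n = 5) in wild type on the log2 scale. Those of hemocyte markers were 7.76 ± 0.62, 6.34 ± 0.34 and 6.12 ± 0.22. Without bgcn arrays 1 and 2, which held the highest accessory gland values, 1674 probe sets changed between Os+bgcn and bgcn, an alternative chosen after seeing the data. With the accessory gland score as covariate the accessory list's median was 0.17, which taking its own score as covariate brings about. The fat body list did not pass (camera adjusted p = 0.067), while the heat shock and general proteasome lists passed downward, the latter also without bgcn arrays 1 and 2, and the JAK-STAT, hub, cyst, early germline, piRNA, replication, EGFR, muscle and hemocyte lists still passed. Genes named above that did not pass with that covariate were hh, Acp53C14b, Acp63F, chinmo, fs(1)Yb, hts, kek1, spi, ihog, sax, Dad, metro, Cyp4g1, Anp, Spn77Bb, Mst57Da, Acp95EF, bt, Mlc1, Pxn, Drs and Lip4. Over all 27 genes of the naming rule whose call ended there without a change of direction, the fold change was at a median of 81.8% of its size without the covariate, while the errors grew. Cyp4g1 stood at -3.13 ± 0.99, Pxn at -1.97, bt at -1.38 and chinmo at 1.08, and Acp95EF at -0.37, while Acp53C14b and Acp63F turned to 0.17 and 0.28.

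**Figure D2:**
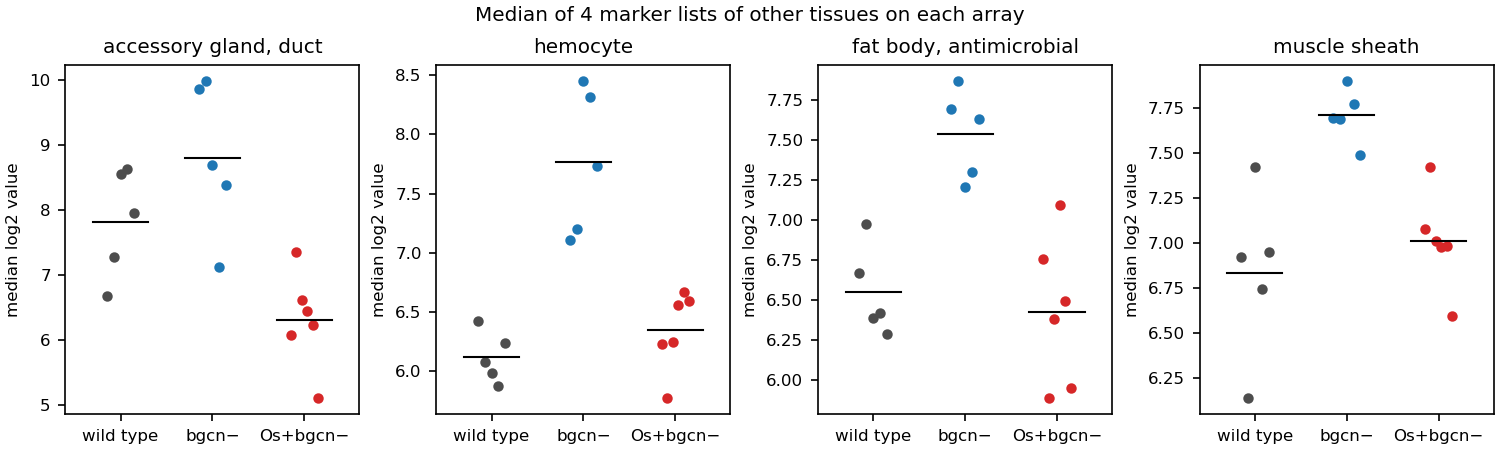
Median log2 value of the accessory gland and duct, hemocyte, fat body and antimicrobial, and muscle sheath lists on each array (points; 5 wild-type, 5 bgcn and 6 Os+bgcn arrays), with a line at the group mean. The accessory gland medians run from 7.12 to 9.98 over the bgcn arrays and from 5.10 to 7.34 over the Os+bgcn arrays, and all 4 lists have their highest group mean in bgcn.

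The lists of later spermatogenesis hardly moved between both mutants. On the log2 scale the mean array medians in bgcn and Os+bgcn were 5.37 and 5.33 for spermatid genes. They were 5.27 and 5.42 for testis-specific proteasome subunits, and 5.44 and 5.69 for testis-type mitochondrial paralogs. In wild type they were 10.4, 8.53 and 9.79. These lists were so dim in both mutants that their small changes say little about an effect of Os. Of 46 spermatid differentiation genes 2 rose, 4 fell and 40 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.36). Among 10 spermatocyte transcription regulators 2 rose, among 16 axonemal dynein and cilium genes 2, among 12 testis-specific proteasome subunits 1 and among 15 testis-type mitochondrial paralogs 1, none fell, the counts were the same adjusted over each list alone, and the camera adjusted p-values were 0.35, 0.66, 0.71 and 1. Of 8 tubulin isotypes none passed on either adjustment, with a median of 0.07 and a camera direction downward (adjusted p = 1). Of 12 pigment cell markers 1 rose on either adjustment (camera adjusted p = 0.40).

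Housekeeping lists moved little between both mutants. Ribosomal centring shifts the fold changes of all probe sets alike and sets the ribosomal list near 0 by construction. Its values therefore show the reach of scaling and do not test a list's direction. The ribosomal array medians it subtracts ran from 11.2 to 12.9 in Os+bgcn and from 11.9 to 13.0 in bgcn. It can thus add spread within groups, and a call can end there through larger errors. Of 31 cytosolic ribosomal protein genes 4 fell and 27 did not pass, with none passing adjusted over the list alone, and the median was -0.37, or -0.15 with quantile normalization and 0.03 with arrays centred on those same genes. It was -0.22 without bgcn array 5 and -0.19 without Os+bgcn array 1. The camera adjusted p of the ribosomal list was 0.00093, but 0.41 with an estimated correlation, and the list did not pass with quantile normalization. Of 45 general oxidative phosphorylation subunits 8 fell and 2 rose, the same adjusted over the list alone, with a median of -0.13 that turned to 0.27 with ribosomal centring. Its camera adjusted p was 0.020, and 0.41 with an estimated correlation. Without bgcn array 3, bgcn array 5 or Os+bgcn array 6 the list did not pass (medians -0.13 to -0.08, adjusted p = 0.053 to 0.14), nor with quantile normalization. COX8, a cytochrome c oxidase subunit, changed by -0.81 ± 0.17, and by -0.41 (adjusted p = 0.305) with ribosomal centring. Of 25 general proteasome subunits 1 fell on either adjustment, Rpt5 at -0.51 ± 0.11 (adjusted p = 0.80 with ribosomal centring). The proteasome list's median of 0.01 and mean of -0.05 differed in sign (camera adjusted p = 0.32), and without bgcn array 1 the median was -0.10 and the list passed downward (adjusted p = 0.045). Of 12 heat shock genes 2 fell on either adjustment, among them the chaperonin paralog Hsp60C at -1.20 ± 0.13, which did not pass with ribosomal centring (adjusted p = 0.062). The heat shock list's camera adjusted p was 0.32, and its median of -0.03 was 0.07 with quantile normalization and 0.37 with ribosomal centring.

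**Figure D3:**
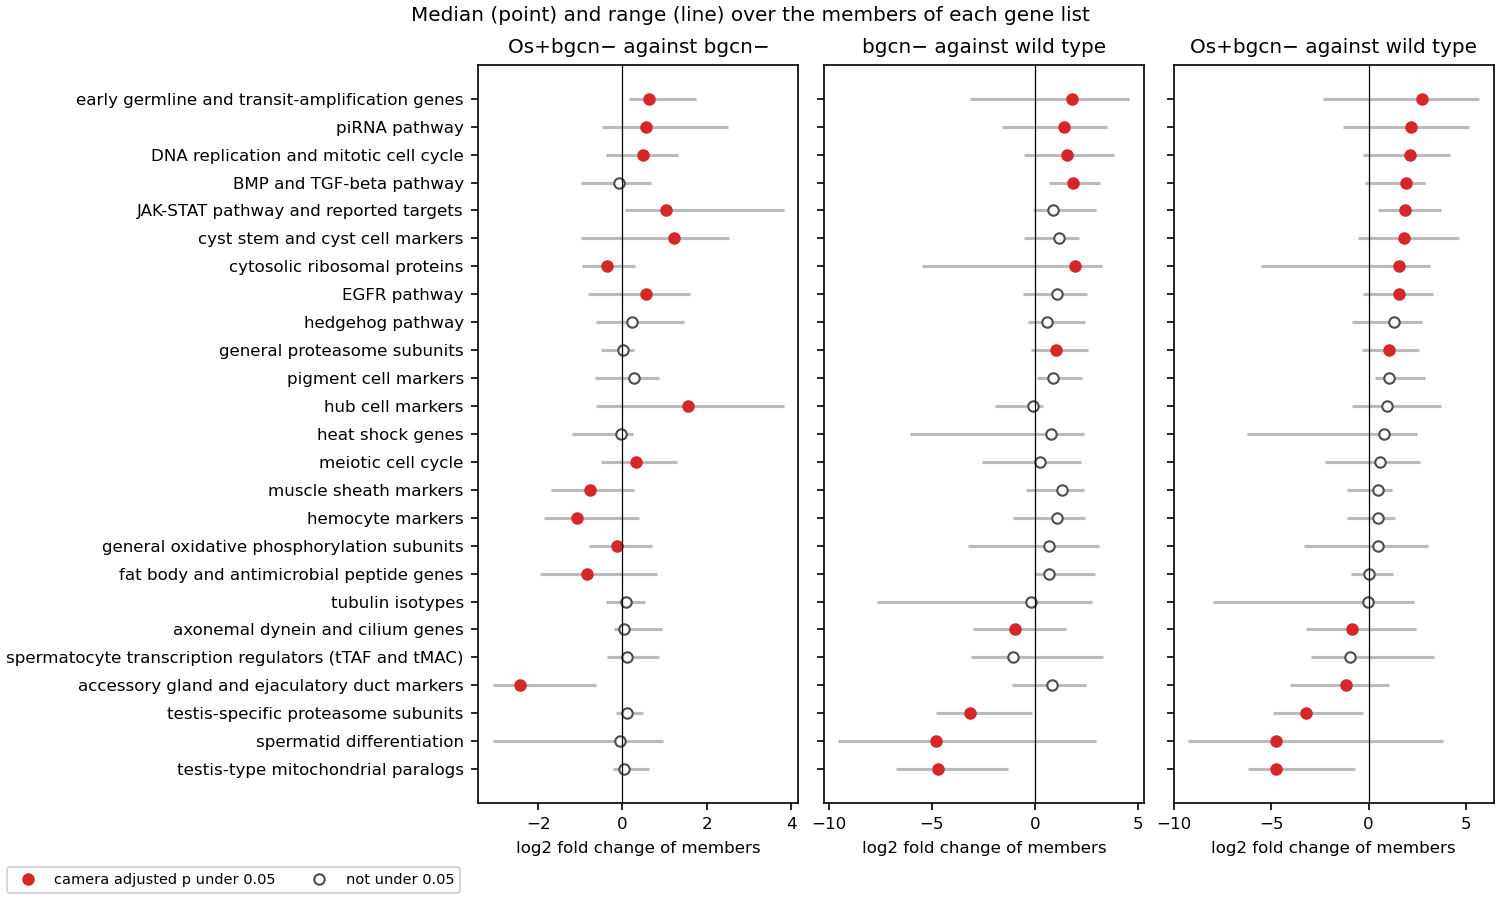
Median (point) and range (line) of the members' log2 fold changes for each of 25 gene lists in the 3 comparisons, with filled points for lists with a camera adjusted p under 0.05. The spermatid differentiation median is -0.06 between both mutants (0.34 with arrays centred on the ribosomal protein genes) and -4.80 and -4.77 against wild type, and the early germline median is 0.64 between both mutants, 1.78 in bgcn (-0.28 with that centring) and 2.74 in Os+bgcn against wild type.

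The comparison of bgcn with wild-type testes set a testis whose germ cells do not enter the spermatocyte stage beside one with all stages. Transcripts of spermatids and of testis-specific organelle and proteasome paralogs were far lower in bgcn, and those of early germ cells were higher, although with arrays centred on the ribosomal protein genes the early germline median was -0.28. Mst84Db, a sperm flagellum protein gene, had a signal of 20 ± 5.94 (SD, n = 5) in bgcn and 28509 ± 3194 (n = 5) in wild type, a change of -9.53 ± 0.30 with a limma adjusted p of 4.8e-16. betaTub85D, the testis-specific beta-tubulin, changed by -7.65 ± 0.23 (adjusted p = 3.2e-16). nanos, a translational repressor of germline stem cells, rose by 4.56 ± 0.22 to 1656 ± 331 from 54.0 ± 22.1 (adjusted p = 4.2e-13), and zpg, a germline gap junction protein, by 4.45 ± 0.19 (adjusted p = 5.1e-14).

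Other large differences in bgcn were as follows. Mst84Dc changed by -8.86 ± 0.24, Mst98Cb by -8.68 ± 0.22, ocn by -8.11 ± 0.15, soti by -7.89 ± 0.23, Mst84Da by -7.62 ± 0.18 and the sperm chromatin protein gene Mst77F by -7.57 ± 0.16. The chromatin remodeller kis rose by 4.43 ± 0.19, but by 0.87 on its other probe set. The nuclear export receptor emb rose by 4.38 ± 0.24, or 2.41 on its other probe set, and the pyrimidine synthesis enzyme r-l by 4.21 ± 0.18. eIF3f1, a translation initiation subunit, rose by 4.44 ± 0.31, lig by 4.32 ± 0.19 and Kots by 4.16 ± 0.16. The arrays of both groups did not overlap in any of these genes. Since values near the background are compressed by the pseudocount, the folds of transcripts that are dim in 1 group are understated.

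In bgcn 7277 of 10422 probe sets (69.8%) changed, 4918 higher and 2359 lower, with 3417 and 1812 by at least 2-fold and 18 and 546 by at least 16-fold. The median of all tested probe sets was 0.46, or 0.32 with quantile normalization, 0.21 with arrays centred on their medians and -1.60 with arrays centred on the ribosomal protein genes, and 67.6%, 62.8%, 59.1% and 3.01% of the changed probe sets were higher. With that last centring, 245 probe sets were higher and 7887 lower, so a list's rise against wild type is given relative to the other genes measured and not as an absolute amount.

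Of 46 spermatid differentiation genes 41 fell, 2 rose and 3 did not pass, the same adjusted over the list alone, with a median of -4.80, or -5.26 relative to the median of all probe sets (camera adjusted p = 7.2e-22, and 0.0026 with an estimated correlation). All 15 testis-type mitochondrial paralogs fell on either adjustment, with a median of -4.72 (camera adjusted p = 1.0e-09, and 0.0026 with an estimated correlation). COX4L changed by -6.73 ± 0.24 and COX5BL by -5.56 ± 0.19. Of 12 testis-specific proteasome subunits 11 fell on either adjustment, with a median of -3.14 (camera adjusted p = 4.7e-07, and 0.0040 with an estimated correlation), led by Prosalpha6T at -4.81 ± 0.24 and Prosbeta4R2 at -4.79 ± 0.20. Of 16 axonemal dynein and cilium genes 10 fell and 1 rose on either adjustment, with a median of -0.98 (camera adjusted p = 0.0078, and 0.034 with an estimated correlation). Bug22, a basal body and axoneme protein gene, changed by -2.94 ± 0.16 and tilB by -2.76 ± 0.23. Of 10 spermatocyte transcription regulators 6 fell and 2 rose on either adjustment, with a median of -1.09 that did not pass (camera adjusted p = 0.090), and it passed without the filter. topi changed by -3.10 ± 0.18 and can by -1.76 ± 0.19, while Nxt1, an RNA export factor, rose by 3.28 ± 0.17. Of 14 meiotic cell cycle genes 6 rose and 5 fell on either adjustment, with a median of 0.24, a mean of -0.07 and a camera direction downward (adjusted p = 0.46). Its median was -0.01 with arrays centred on their medians and -1.82 with ribosomal centring. The translation factor bol changed by -2.33 ± 0.15, the cell cycle inhibitor rux by -2.56 ± 0.13 and the cohesion gene ord by 2.23 ± 0.19, the last not passing with ribosomal centring (adjusted p = 0.64).

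Of 16 early germline genes 12 rose and 1 fell in bgcn on either adjustment, with a median of 1.78, or 1.32 above all probe sets, which was -0.28 with ribosomal centring (camera adjusted p = 0.013, and 0.037 with an estimated correlation). vas, a germline helicase gene, rose by 3.57 ± 0.14. Of 24 piRNA pathway genes 19 rose and 3 fell on either adjustment, with a median of 1.41 that was -0.64 with ribosomal centring (camera adjusted p = 0.0055, and 0.034 with an estimated correlation). qin rose by 3.47 ± 0.20 (0.68 on its other probe set), shu by 3.40 ± 0.23 and aub by 3.33 ± 0.28. Of 48 replication and mitotic genes 40 rose and 2 fell, 41 and 2 adjusted over the list alone, with a median of 1.54 that was -0.51 with ribosomal centring (camera adjusted p = 7.6e-06, and 0.0064 with an estimated correlation). CycE rose by 3.84 ± 0.17, the condensin gene glu by 3.46 ± 0.16 and PCNA by 3.01 ± 0.16. Of 14 BMP and TGF-beta genes 12 rose on either adjustment, with a median of 1.82 that was -0.24 with ribosomal centring (camera adjusted p = 0.0033, and 0.063 with an estimated correlation). The type II receptor gene put rose by 3.13 ± 0.23 and the ligand gene myo by 2.87 ± 0.28, while gbb, at 2.12 ± 0.20, did not pass with ribosomal centring (adjusted p = 0.88).

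Most housekeeping genes rose against wild type under the authors' scaling, and the list medians were below 0 with ribosomal centring. Of 31 ribosomal protein genes 29 rose and 2 fell on either adjustment, with a median of 1.95, which was -0.10 with arrays centred on those same genes (camera adjusted p = 0.00043, and 0.36 with an estimated correlation). RpS29 rose by 3.23 ± 0.18, and those that fell were RpL10Aa at -5.50 ± 0.20 and RpS28a at -3.27 ± 0.18, both paralogs of other ribosomal protein genes. Of 25 general proteasome subunits 19 rose on either adjustment, with a median of 1.00 that was -1.05 with ribosomal centring (camera adjusted p = 0.0026, and 0.26 with an estimated correlation). Rpn12 rose by 2.57 ± 0.14 and Rpt3 by 2.29 ± 0.25, and neither passed with ribosomal centring (adjusted p = 0.13 and 0.52). Of 45 general oxidative phosphorylation subunits 27 rose and 7 fell on either adjustment, with a median of 0.65 that was -1.41 with ribosomal centring and did not pass (camera adjusted p = 0.074, and 0.48 with an estimated correlation). It passed without bgcn array 1 (adjusted p = 0.040), with quantile normalization and without the filter. ATPsynC rose by 3.10 ± 0.17, or 0.82 on its other probe set, and COX7C changed by -3.22 ± 0.18. Of 12 heat shock genes 6 rose and 4 fell on either adjustment, with a median of 0.75 and a mean of -0.17 (camera adjusted p = 0.81), and the median was -1.30 with ribosomal centring. Among them Hsp60B changed by -6.05 ± 0.24, Hsp60C by -5.05 ± 0.14 and the chaperone cofactor stv by 2.36 ± 0.20, the last not passing with ribosomal centring (adjusted p = 0.45). Of 8 tubulin isotypes 3 rose and 3 fell on either adjustment (camera adjusted p = 0.40), and betaTub56D rose by 2.73 ± 0.25.

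None of the JAK-STAT, cyst, hub, EGFR, hedgehog and pigment cell lists passed camera in bgcn, and their medians above 0 were all negative with ribosomal centring. JAK-STAT genes rose in 8 of 10 cases with a median of 0.86 (-1.19 with ribosomal centring; camera adjusted p = 0.095), and Stat92E, the pathway's transcription factor, rose by 2.94 ± 0.23. Cyst markers rose in 8 of 12 cases and fell in 1, with a median of 1.16 (-0.89; adjusted p = 0.18). zfh1, apt and Nrt rose by 2.12 ± 0.27, 2.12 ± 0.17 and 2.10 ± 0.25, but these 3 did not pass with ribosomal centring (adjusted p = 0.87, 0.87 and 0.90). Of 5 hub markers only CadN passed, at -1.93 ± 0.25, and the median was -0.09 (adjusted p = 0.46). EGFR genes rose in 10 of 13 cases with a median of 1.06 (-0.99; adjusted p = 0.095), hedgehog genes in 5 of 10 with 0.58 (-1.48; adjusted p = 0.40) and pigment cell markers in 8 of 12 with 0.88 (-1.18; adjusted p = 0.13). smo, at 2.42 ± 0.22, and ca, at 2.28 ± 0.19, did not pass with ribosomal centring (adjusted p = 0.36 and 0.58). In all 6 of these lists the counts were the same adjusted over the list alone.

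Markers of other tissues stood as follows in bgcn against wild type. Muscle sheath markers rose in 13 of 17 cases, also 13 adjusted over the list alone, with a median of 1.29 (-0.76 with ribosomal centring; camera adjusted p = 0.062, and 0.25 with an estimated correlation). The muscle list passed with quantile normalization, without the filter and in a fit of both compared groups alone, and without bgcn arrays 1 and 2, as well as without bgcn array 1, Os+bgcn array 2, Os+bgcn array 6 or wild-type array 3 (adjusted p = 0.041 to 0.050). Hemocyte markers rose in 8 of 11 cases and fell in 2 on either adjustment, with a median of 1.07 (-0.99; adjusted p = 0.29). Fat body and antimicrobial genes rose in 5 of 12, 4 adjusted over the list alone, with a median of 0.66 (-1.40; adjusted p = 0.40). bt, Mlc2, crq, Hml and Drs rose by 2.38 ± 0.26, 2.32 ± 0.23, 2.41 ± 0.22, 2.19 ± 0.26 and 2.14 ± 0.27, and none of these 5 passed with ribosomal centring (adjusted p = 0.36 to 0.84). Lip4 rose by 2.91 ± 0.28. Accessory gland and duct markers rose in 3 of 17 cases and fell in 1, or 3 and 0 adjusted over the list alone, with a median of 0.81 (-1.25; camera adjusted p = 0.67). Gld rose by 1.70 ± 0.22 and EbpIII by 1.31 ± 0.38, which turned to -0.35 and -0.75 with ribosomal centring.

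The comparison of Os+bgcn with wild type set the mutant testis that also carries Os beside the normal testis. Spermatid transcripts were far lower, and early germline, piRNA, JAK-STAT and cyst cell genes were higher. nanos rose by 5.69 ± 0.21 to 3680 ± 955 (SD, n = 6) from 54.0 ± 22.1 (n = 5), with a limma adjusted p of 5.8e-15, and piwi by 5.15 ± 0.18 to 1367 ± 184 from 21.4 ± 12.5. The nucleolar protein gene mod rose by 4.68 ± 0.14, Nrt by 4.63 ± 0.24 (1.85 on its other probe set) and magu by 4.51 ± 0.28. Mst84Dc changed by -9.27 ± 0.23 (adjusted p = 1.2e-17) and S-Lap7, a sperm leucyl aminopeptidase gene, by -8.11 ± 0.25 (adjusted p = 3.1e-16).

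In Os+bgcn 7446 of 10422 probe sets (71.4%) changed, 4925 higher and 2521 lower, with 3553 and 1880 by at least 2-fold. The median of all tested probe sets was 0.43, or 0.27 with quantile normalization, 0.15 with arrays centred on their medians and -1.23 with ribosomal centring, where 789 were higher and 6661 lower and the higher share went from 66.1% to 10.6%. Of the JAK-STAT genes 10 of 10 rose on either adjustment, upd1 among them, with a median of 1.87 (camera adjusted p = 0.0023, and 0.012 with an estimated correlation). Stat92E rose by 3.65 ± 0.22 and apt by 3.43 ± 0.16. Cyst markers rose in 10 of 12 cases and fell in 1, or 11 and 1 adjusted over the list alone, with a median of 1.83 (camera adjusted p = 0.013, and 0.033 with an estimated correlation). aop rose by 3.32 ± 0.20 and zfh1 by 3.21 ± 0.25. Early germline genes rose in 14 of 16 cases and fell in 1, with a median of 2.74 (camera adjusted p = 0.00062, and 0.0055 with an estimated correlation). vas rose by 4.22 ± 0.13 and zpg by 4.81 ± 0.18. piRNA genes rose in 20 of 24 cases and fell in 2, with a median of 2.19 (camera adjusted p = 1.0e-04, and 0.0048 with an estimated correlation). Among them aub rose by 4.44 ± 0.27 and qin by 4.21 ± 0.19, or 0.88 on its other probe set. Replication and mitotic genes rose in 43 of 48 cases, with a median of 2.12 (camera adjusted p = 5.1e-08, and 0.0020 with an estimated correlation), with glu at 4.18 ± 0.16, Mcm3 at 4.05 ± 0.23 and SMC2 at 3.93 ± 0.13. The germline, piRNA and replication counts were the same adjusted over each list alone. With ribosomal centring the medians were 0.21 for JAK-STAT, 0.17 for cyst, 1.08 for early germline, 0.53 for piRNA and 0.47 for replication genes.

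Among signalling lists in Os+bgcn against wild type, BMP and TGF-beta genes rose in 11 of 14 cases on either adjustment, with a median of 1.90, or 0.24 with ribosomal centring (camera adjusted p = 0.012, and 0.097 with an estimated correlation). put rose by 2.91 ± 0.22 and myo by 2.79 ± 0.27. EGFR genes rose in 11 of 13 cases on either adjustment, with a median of 1.54 that was -0.11 with ribosomal centring (camera adjusted p = 0.013, and 0.033 with an estimated correlation), and spi rose by 3.08 ± 0.17. Hedgehog genes rose in 7 of 10 cases and fell in 1 on either adjustment, with a median of 1.31 that was -0.35 with ribosomal centring (camera adjusted p = 0.20), with smo at 2.76 ± 0.21. Hub markers rose in 4 of 5 cases, upd1 among them, and fell in 1 on either adjustment. Their median was 0.95, and -0.70 with ribosomal centring (camera adjusted p = 0.32). dlg1 rose by 1.63 ± 0.16 and shg, the E-cadherin gene, by 0.95 ± 0.16, and with ribosomal centring these were -0.03 and -0.70.

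The lists of later spermatogenesis were also far lower in Os+bgcn than in wild type. Of 46 spermatid genes 43 fell and 2 rose, with a median of -4.77 (camera adjusted p = 2.8e-21, and 0.0020 with an estimated correlation). All 15 testis-type mitochondrial paralogs fell, with a median of -4.77 (camera adjusted p = 6.3e-09, and 0.0020 with an estimated correlation), and 11 of 12 testis-specific proteasome subunits, with a median of -3.22 (camera adjusted p = 1.3e-06, and 0.0044 with an estimated correlation). COX4L changed by -6.18 ± 0.23 and Prosbeta4R2 by -4.91 ± 0.19. Axonemal genes fell in 10 of 16 cases and rose in 1, with a median of -0.84 (camera adjusted p = 0.012, and 0.033 with an estimated correlation). With ribosomal centring that list's median was -2.49 and it did not pass (adjusted p = 0.062). Spermatocyte regulators fell in 6 of 10 cases and rose in 2, with a median of -0.98 (camera adjusted p = 0.17, past the threshold without the filter), topi at -2.98 ± 0.17 and Taf12L at -1.81 ± 0.18. The counts of these 5 lists were the same adjusted over each list alone. Meiotic genes rose in 8 of 14 cases and fell in 4 on either adjustment, with a median of 0.60 that was -1.06 with ribosomal centring (camera adjusted p = 0.98).

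Other lists in Os+bgcn against wild type included those of housekeeping genes and other tissues. Ribosomal protein genes rose in 27 of 31 cases and fell in 2 on either adjustment, with a median of 1.55 that was -0.10 with arrays centred on them (camera adjusted p = 0.0049, and 0.51 with an estimated correlation). General proteasome subunits rose in 20 of 25 cases and fell in 1 on either adjustment, with a median of 1.03 that was -0.63 with ribosomal centring (camera adjusted p = 0.0065, and 0.34 with an estimated correlation). General oxidative phosphorylation subunits rose in 25 of 45 cases and fell in 9 on either adjustment, with a median of 0.47 that was -1.19 with ribosomal centring (camera adjusted p = 0.24), and the list passed with quantile normalization. Heat shock genes rose in 7 of 12 cases and fell in 4, with a median of 0.81, a mean of -0.28 and -0.85 with ribosomal centring (camera adjusted p = 0.88). Tubulin isotypes rose in 3 of 8 cases and fell in 4, with a median of -0.04 that was 0.16 with quantile normalization (camera adjusted p = 0.57). Accessory gland markers fell in 11 of 17 cases and rose in 1, or 12 and 1 adjusted over the list alone, with a median of -1.15 (camera adjusted p = 0.021, and 0.52 with an estimated correlation). Acp95EF changed by -4.06 ± 0.46 and SP, the sex peptide gene, by -2.40 ± 0.41. With that list's own score as covariate the median was 0.10 by construction.

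Muscle markers rose in 6 of 17 cases and fell in 1 in Os+bgcn against wild type on either adjustment, with a median of 0.50 that was -1.16 with ribosomal centring (camera adjusted p = 0.73). Hemocyte markers rose in 3 of 11 and fell in 2 on either adjustment, with a median of 0.47, -1.18 with ribosomal centring, a mean of 0.22 and a camera direction downward (adjusted p = 0.97). The hemocyte genes crq and Col4a1 rose by 1.34 ± 0.21 and 1.12 ± 0.15, and were -0.32 and -0.53 with ribosomal centring. Fat body genes rose in 2 of 12 and fell in 1, or 2 and 0 adjusted over the list alone, with a median of 0.01, which was -0.15 with quantile normalization, -0.27 with arrays centred on their medians and -1.65 with ribosomal centring (camera adjusted p = 0.73). Pigment cell markers rose in 8 of 12 cases on either adjustment, with a median of 1.03 that was -0.63 with ribosomal centring (camera adjusted p = 0.081).

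The 3 comparisons share arrays, so their overlaps were set beside what sharing gives. In Os+bgcn 986 probe sets were higher than in both other groups, against 572.7 for independent lists of the same sizes. In 100 simulations without any effect it was 0, which follows by design, since few probe sets are called there. It was 658 when the Os+bgcn arrays were split between the comparisons. That split left 861 and 4690 higher probe sets instead of 1212 and 4925, so fewer arrays lower the count too. Lower in both mutants than in wild type were 2115 probe sets, against 570.6 for independent lists and 0 in the simulations. With the wild-type arrays split it was 1921, from 2111 and 2425 lower probe sets instead of 2359 and 2521. Higher in both mutants were 4251. None of these reference values measures an effect that both comparisons share. Fold changes of bgcn and Os+bgcn against wild type correlated at 0.95 across probe sets, against 0.52 simulated without effects, with a covariance of 3.53 against 0.0345. Those of Os+bgcn against bgcn and against wild type correlated at 0.27, against 0.45 simulated, with a covariance of 0.310 against 0.0286. With ribosomal centring 349 probe sets were higher in Os+bgcn than in both others and 6373 lower in both mutants than in wild type, and with the accessory gland covariate 128 were higher in Os+bgcn than in both.

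X-linked genes were tested among the changed genes with Fisher's exact test, two-sided, in 6 tests, with genes not being independent replicates. Of genes higher in Os+bgcn than in bgcn 138 of 1022 were X-linked, against 1284 of 7539 other tested genes (odds ratio 0.76, exact p = 0.0041, adjusted p = 0.012), and of genes lower 96 of 790 against 1326 of 7771 (odds ratio 0.67, exact p = 0.00030, adjusted p = 0.0018). Among genes changed by at least 2-fold the odds ratio was 1.21 for those higher (exact test, adjusted p = 0.26) and 0.58 for those lower (adjusted p = 0.0053). Among genes higher in bgcn than in wild type the odds ratio was 0.86 (exact p = 0.011, adjusted p = 0.023) and among those lower 0.87 (exact p = 0.045, adjusted p = 0.067). Against wild type the odds ratios of Os+bgcn were 0.93 for higher genes (exact p = 0.20, adjusted p = 0.20) and 0.89 for lower genes (exact p = 0.084, adjusted p = 0.10).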

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

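The check of how the members of each tissue list correlate among themselves, the comparison of scaling references for the share of higher probe sets, the fit without bgcn arrays 1 and 2 and the fit with the accessory gland covariate were chosen only after the result was seen. In groups of 5 or 6 arrays, an array was marked when its gap to the nearest other was large against the group's range (Dixon's test at 95%). This marked 20 of 450 groups, where chance gives about 22.5, or 1 in 20. Array bgcn 1 holds 4 of them and Os+bgcn 2 holds 3.

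The mean correlation of bgcn 1 with its group was 0.885, against 0.911 to 0.921 for the other bgcn arrays. List medians stood apart for replication and mitotic genes on Os+bgcn 6 (8.58, others 8.18 to 8.32), general proteasome subunits on Os+bgcn 6 (9.77, others 9.92 to 9.97), heat shock genes on bgcn 1 (8.41, others 9.32 to 9.61) and hedgehog genes on bgcn 5 (6.08, others 6.61 to 6.80). Among genes, the Os+bgcn arrays that stood apart were array 1 for Cks30A (281.3), array 2 for Anp (436.9), Spn77Bb (168.0) and zfh1 (579.7), array 3 for SMC2 (704.5), array 4 for Hsp60B (44.8), and array 5 for ATPsynbeta (700.3) and COX5BL (22.6). The bgcn arrays were array 1 for spi (208.8) and zpg (899.2), array 2 for put (532.2), array 4 for dlg1 (12.4) and array 5 for Uhg1 (34.0). Those of wild type were array 1 for hts (20.1) and array 3 for mod (41.9).

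Of the 929 probe sets lower in Os+bgcn than in bgcn, 891 lie outside the tissue lists, and RNA of other tissues in the bgcn samples is a candidate source of their signal. A median correlation with a tissue score under 0.2 over the 5 bgcn arrays had been set in advance as the bound against that tissue. It was 0.163 for the accessory gland (0.0893 to 0.236 with an array left out; random sets of equal brightness -0.102 to 0.0696), 0.184 for hemocytes and fat body (0.0557 to 0.266; random -0.125 to 0.0618) and -0.159 for muscle (-0.247 to 0.0416; random -0.0464 to 0.102). All 3 lie under the bound, the first 2 with ranges that cross it. Members correlated with the rest of their list at medians of 0.764 for accessory gland, 0.190 for hemocytes and fat body and -0.0498 for muscle. The last 2 scores thus hardly track an amount of tissue over these arrays, and RNA of any of these tissues stays open. None of these 3 sources can be told apart from an effect of the genotype, since 5 arrays are few and the bgcn samples alone came from 750 testes. Acp95EF was at 4831 ± 2155 in wild type, 2350 ± 1129 in bgcn and 317 ± 193 in Os+bgcn, and a biological effect of Os on these transcripts was not tested apart from the amount of tissue.

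More of the changed probe sets were higher than lower in bgcn against wild type, 67.6%. Scaling of each array on a mean pulled up by a few abundant transcripts is a candidate explanation. With arrays centred on their medians the share was 59.1% (58.6 to 59.3% with an array left out), above the 55% set in advance as the bound against it. That bound was wrong, because the centring itself moves the balance of higher and lower probe sets, and with ribosomal centring 3.01% were higher. The share therefore does not decide the cause, and scaling stays open. The loss of spermatid transcripts could raise the share of all others in equal amounts of RNA, and this was not tested.

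The arrays were also regrouped at random into groups of the same sizes, 100 splits for each result with the real 1 included. Chance can be excluded for the 2141 probe sets changed between both mutants, where 1 split reached that count (highest other 155), for the 7277 in bgcn against wild type (1; highest other 2553) and for the 7446 in Os+bgcn against wild type (1; highest other 6420, in a split that keeps 1 of 6 Os+bgcn arrays in place and so nearly swaps the groups). It can be excluded for the 2115 probe sets lower in both mutants (1, highest other 1242). For the 986 higher in Os+bgcn than in both others, 2 splits reached the count, under the bound set in advance. The highest other split gave 1818, again keeping 1 of 6. The other arrays in its Os+bgcn group came from wild type or bgcn, and the 2115 probe sets lower in both mutants are higher in wild type. Such a split can therefore carry real differences between genotypes and is no reference for chance. The splits thus cannot decide about chance for the 986, and why that split exceeded the real one was not tested. For the number of gene lists that passed between both mutants, 4 splits reached the 14 lists, also under that bound. The highest other split gave 16 and kept 2 of 6 Os+bgcn arrays in place, so chance is not firmly excluded for that number of lists. In bgcn against wild type 25 splits reached the 10 lists. The highest other gave 14, with 4 of 5 arrays of each group still together. In Os+bgcn against wild type 26 splits reached the 14 lists (highest other 16, keeping 2 of 6). By the bound set in advance chance is not excluded for these 2 counts. These splits mix groups that differ at 69.8% and 71.4% of probe sets, so they can still carry much of the real difference. They are no reference without effects, cannot decide about the 986 or about the number of lists, and test no single list.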

How the results depend on the processing

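The fit without bgcn arrays 1 and 2 and the fit with the accessory gland covariate were chosen only after the result was seen. Over the named genes that passed, 5562 of 5665 alternative values kept direction and call, 94 lost the call and 9 changed direction. Over the lists that passed, 1158 of 1178 kept both, 7 lost the call and 13 changed direction. These values are not independent, since many come from fits that leave out 1 array and share the others. With the covariate 27 named genes lost the call between both mutants, 2 changed direction and 27 did neither. With ribosomal centring 15 lost it in bgcn against wild type, 2 changed direction, 2 gained it and 47 did none of these. Of genes that did not pass, 115 of 124 values kept direction and side of the threshold, 7 gained the call and 2 changed direction; of such lists, 1037 of 1147 kept both, 17 gained it and 93 changed direction. With an array left out, 1700 to 2130, 7056 to 7318 and 7258 to 7569 probe sets changed in the 3 comparisons, and 751 to 995 and 2058 to 2120 were higher in Os+bgcn than in both others and lower in both mutants. The number of arrays and the signal over background limit the dim transcripts.

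With ribosomal centring the overlaps were 349 (986) and 6373 (2115), and the bgcn transcript differed from wild type by -2.55 in bgcn and -1.92 in Os+bgcn and upd1 by -2.14 in bgcn. This centring shifts the fold changes of all probe sets of a contrast alike, and can also add spread between the arrays of a group. Of 25 list medians 5, 18 and 12 changed direction in the 3 comparisons, which follows from the shift and from where each median lay. Among lists that had passed, these were oxidative phosphorylation 0.27 and ribosomal proteins 0.0254 between both mutants; early germline -0.28, piRNA -0.64, proteasome -1.05, ribosomal proteins -0.10, replication -0.51 and BMP -0.24 in bgcn; and proteasome -0.63, ribosomal proteins -0.10 and EGFR -0.11 in Os+bgcn. So did the genes Gld (-0.35) and EbpIII (-0.75) in bgcn and dlg1 (-0.0303), shg (-0.70), Zasp52 (-0.47), crq (-0.32) and Col4a1 (-0.53) in Os+bgcn. The bgcn transcript passed in bgcn at -0.74 with quantile normalization and -0.74 with median centring (-0.64 to -0.39 with an array left out).

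The proteasome median between both mutants was -0.10 to 0.0559 with an array left out, -0.20 without bgcn arrays 1 and 2 and -0.23 with the covariate, and the list passed in both of these fits. With the covariate 351 probe sets changed between both mutants and 128 were higher in Os+bgcn than in both; larger errors go with this (0.196 to 0.348). By construction, the accessory gland medians were then near 0, at 0.17 and 0.10 in Os+bgcn against bgcn and wild type, and Acp53C14b and Acp63F 0.17 and 0.28 against bgcn. Among calls of at least 2-fold the odds ratio of X linkage for genes higher than in bgcn was 1.21. Apart from the covariate's errors, the cause was not tested. The fit with replicate number as a block used replicates 1 to 5, so it also left out Os+bgcn array 6. In it 1748, 7251 and 7310 probe sets changed. Between both mutants hh, dpp and ND-B8 did not pass, and the muscle list passed in bgcn. Leaving out Os+bgcn array 6 alone also changed the calls of hh, ND-B8 and the muscle list, so these cannot be put down to the block. Paired by replicate number, 1, 1 and 2 of 5 arrays correlated best with their own number (r -0.11 to 0.20, -0.09 to 0.05 and -0.04 to 0.05).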

Other observations

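Outside the genes named by the rule, and chosen after their values were seen, several transcripts had a lower mean signal in bgcn than in both other groups. BigH1, a germline linker histone gene, had a signal of 82.8 ± 29.1 (SD, n = 5) in wild type, 6.66 ± 2.19 (n = 5) in bgcn and 119 ± 33.5 (n = 6) in Os+bgcn. It changed by -1.95 ± 0.22 in bgcn and differed by 0.45 (adjusted p = 0.062) in Os+bgcn against wild type. NT5E-2, a nucleotidase gene, stood at 146 ± 41.5, 19.5 ± 16.5 and 189 ± 48.9. exu, an mRNA localization gene, stood at 2241 ± 598, 20.9 ± 11.3 and 96.0 ± 21.0, far below wild type in both mutants. Lower in bgcn than in both other groups were 211 probe sets, against 274.3 for independent lists.

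MtnA, a metallothionein gene also chosen after its values were seen, had a signal of 15727 ± 1958 in wild type, 32480 ± 16696 in bgcn and 6655 ± 2302 in Os+bgcn. It changed by -2.23 ± 0.33 between Os+bgcn and bgcn (adjusted p = 6.8e-05) and by -1.32 ± 0.33 between Os+bgcn and wild type (adjusted p = 0.0013).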
